A study of Mus musculus with 12 samples.

How the data were processed

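RNA was sequenced from 12 libraries of sorted mouse leukaemia cells, 3 in each of 4 groups (PBS, CpG1668, Dox and CpG1668+Dox). Each deposited file lists 33531 gene symbols with RPKM values (reads scaled to gene length and library size) made by the authors. The submitters' processing notes name STAR 2.7.9, Partek 7.18.0723 and the mouse genome build mm10, without saying which step each tool did. The annotation, the filters and the quantification settings are not given in the sources used here. Read counts were not used here.

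The summed RPKM ran from 358132.9 to 382549.7 per library, so the values had not been rescaled to a fixed total. Values above 0 went down to 1.4e-45, as values do when an estimating algorithm shares reads out between genes, so whole reads cannot be recovered for each gene. The depth was estimated from genes with a single annotated transcript. The commonest value of RPKM times transcript length was taken as the step of 1 read. That step was refined by least squares on values near its whole multiples, up to 10 reads. The depth that the step implies came to 30440000 to 35020000 reads per library. At that size 72.2% to 73.5% of the 4852 to 5188 genes used lay within 0.05 of a whole read. A gene of 1 kb with 3 reads would then have an RPKM of 0.086 to 0.099. This limit covers counting error alone, and RNA reads without molecular tags are not independent molecules. Of the symbols, 32391 (96.6%) were found in GENCODE M21 (GRCm38), which gave identifiers and positions for genes named in the text.

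The choices below were made before the data were examined, except those said to have been added later. Groups came from the sample titles. Genes with a mean RPKM of at least 1 over the 12 libraries were kept (12167 genes), and log2(RPKM + 1) was fitted with limma 3.58.1 in R 4.3.3. The pseudocount of 1 shrinks the fold changes of genes with low RPKM, so ratios of group means are given beside some of them. A single model with 4 group means was fitted to the 12 libraries (8 residual degrees of freedom), with an intensity trend in the empirical Bayes step. The 6 planned contrasts were CpG1668 against PBS, Dox against PBS, CpG1668+Dox against PBS, against CpG1668 and against Dox, and the interaction. P-values were adjusted by the Benjamini-Hochberg method over the genes of each contrast, and a gene was called at an adjusted p under 0.05. The contrast of CpG1668 against Dox was added after the data were seen.

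Gene groups were tested as 36 lists fixed before the data were examined, of which 31 had at least 5 kept members and were tested and 5 were not. The test was limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 31 lists of each contrast. Each list was also tested with a correlation estimated from the residuals, and with fry. Fry asks whether the genes of a list move, on balance, one way, and does not compare the list with other genes. The count of called members is given over all genes and adjusted over the list alone.

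The genes named in the text followed a rule fixed beforehand. It always took genes fixed by name, among them Stat3, Irf8, Tlr9 and Cbfb. Some genes that the rule took are not reported here. For each pairwise contrast it took the 8 largest positive and the 8 largest negative log2 changes among called genes with a mean RPKM of at least 5 in the higher group and no overlap between replicates, leaving out predicted gene models and pseudogenes. For the interaction it took the 8 called genes with the smallest p. It also took, for each contrast and list, up to 4 members with the largest moderated t statistic in either direction. Where fewer than 3 genes were called in a direction, the 3 with the smallest p were taken and are said not to pass. Counts of 5 or fewer may be named in full. Other genes are said to have been chosen after their values were seen.

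Alternatives covered the pseudocount (0.1), the filter (none, or a mean RPKM of at least 5), median-of-ratios scaling, quantile normalization, no intensity trend, a fit of only the groups compared, a replicate block, and leaving out each library in turn. Covariates for the mean of the late neutrophil genes and for the mean of the Y-linked genes were added after the data were seen. The pipeline was tested on simulated data with 50 changed genes at each of 4 fold changes. In CpG1668 against PBS it recovered 52% at 1.25-fold, 80% at 1.5-fold, 98% at 2-fold and 98% at 4-fold, with 6 false calls. For the interaction it recovered 34%, 72%, 86% and 94%, with 1 false call. False calls made up 3.5% of the calls in CpG1668 against PBS, 4% in Dox against PBS, 6.2% (11 calls) in CpG1668+Dox against PBS, 5.7% (10 calls) in CpG1668+Dox against CpG1668, 4.5% in CpG1668+Dox against Dox and 0.7% in the interaction, so 2 of the 6 lay above the threshold of 5%. The single list raised was called, and 0 of the 30 unchanged lists were. The simulated genes varied independently of each other, whereas the estimated correlation reached 0.887 for the late neutrophil genes. The simulation therefore cannot show how often camera calls unchanged lists of correlated genes. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.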

Results

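The data were RPKM values of mouse acute myeloid leukaemia cells that carry the inv(16) fusion, a rearrangement that joins Cbfb to a myosin gene. The line, CMM-tetON-shStat3, holds a hairpin RNA against Stat3 that doxycycline (Dox) switches on, and marks its cells with GFP and mCherry. Cells were injected into the veins of immunodeficient NSG mice, and treatment began at about 1% leukaemia cells in the blood. Mice received PBS, CpG1668 (a DNA oligonucleotide that activates the receptor TLR9), Dox, or both. The labels disagree on the schedule, which was 6 daily treatments in one place and 3 treatments every other day in another. Cells positive for GFP and mCherry were sorted from spleens 1 day after the last treatment, and RNA was sequenced. Each group had 3 libraries, with an estimated depth of 30440000 to 35020000 reads. From 11945 to 12454 genes per library had an RPKM of at least 1. The labels do not say that the libraries of a group came from separate mice, so p-values measure only the spread between libraries. Values below are mean RPKM ± SD of 3 libraries, and changes given with an adjusted p are log2 fold changes from limma.

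The series asks about the inhibition of STAT3 and the TLR9-driven differentiation of these cells through Irf8. The Stat3 transcript (ENSMUSG00000004040.16, chromosome 11, 100885098 to 100939540, minus strand) was not lower in libraries labelled with Dox. It was 17.2 ± 0.576 in PBS, 18.2 ± 0.483 in CpG1668, 18.9 ± 0.173 in Dox and 19.4 ± 0.331 in CpG1668+Dox. The PBS libraries had 17.9, 16.8 and 16.9 RPKM, the CpG1668 libraries 17.6, 18.5 and 18.4, the libraries labelled Dox 18.8, 19.1 and 18.8, and those labelled CpG1668+Dox 19.7, 19.4 and 19.0. The 6 libraries with a Dox label exceeded the 6 without by 0.11 on the log2 scale, with means of 19.1 ± 0.342 and 17.7 ± 0.716. A two-sided exact permutation test within the CpG1668 strata gave p = 0.005, the smallest that its 400 arrangements allow. With limma, Stat3 was higher in Dox than in PBS (log2 change 0.13, adjusted p = 0.044) and in CpG1668+Dox than in PBS (0.16, adjusted p = 0.0068), and its interaction was -0.04 (adjusted p = 0.946). Because the transcript was not lower, each comparison below is between libraries as labelled.

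Irf8 (ENSMUSG00000041515.10, chromosome 8, 120736358 to 120756694, plus strand) was low in PBS and higher in each treated group, at 0.376 ± 0.0802 in PBS, 1.61 ± 0.0536 in CpG1668, 1.16 ± 0.0685 in Dox and 2.89 ± 0.614 in CpG1668+Dox. Tlr9 (ENSMUSG00000045322.10, chromosome 9, 106222598 to 106226883, plus strand) was below the filter in mean RPKM, at 0.0991 ± 0.0617 in PBS, 0.326 ± 0.036 in CpG1668, 0.196 ± 0.0345 in Dox and 0.445 ± 0.0799 in CpG1668+Dox. Fitted without the filter, it was higher in CpG1668 than in PBS (log2 change 0.27, adjusted p = 0.033) and in CpG1668+Dox than in PBS (0.39, adjusted p = 0.0015). Cbfb (ENSMUSG00000031885.14, chromosome 8, 105170674 to 105217989, plus strand) was at 30.3 ± 1.84 in PBS, 30.3 ± 1.1 in CpG1668, 31.7 ± 0.768 in Dox and 31.7 ± 1.16 in CpG1668+Dox, and was not called in the 6 planned contrasts.

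The largest axis of variation put the untreated and the doubly treated libraries at opposite ends. The first principal component held 52.5% of the variance, with PBS at -21.69 to -19.13, CpG1668 at 0.79 to 3.86, Dox at -3.34 to 4.96 and CpG1668+Dox at 14.13 to 20.77. In 11 of 12 libraries the best correlated library was of the same group. The exception was Dox 1, which matched CpG1668 3. Pearson r across genes was 0.992 to 0.996 within groups and 0.97 to 0.994 between groups, and 0 pairs of files were identical.

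**Figure D1:**
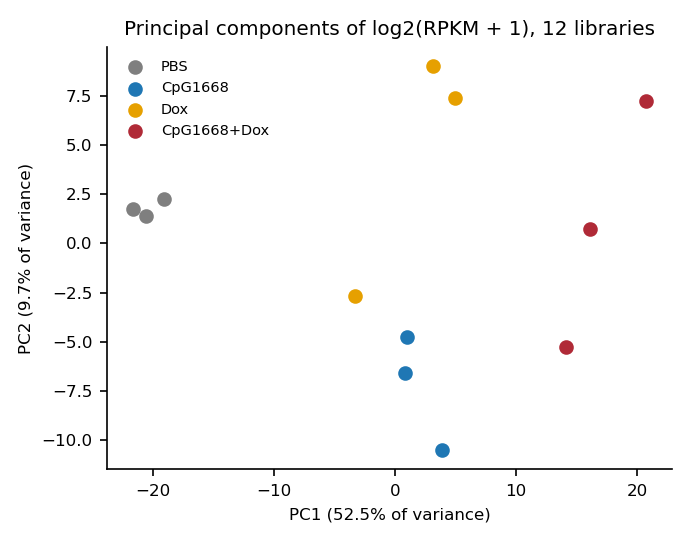
First and second principal components (52.5% and 9.7% of the variance) of log2(RPKM + 1) for 12 libraries, with 1 point per library coloured by group. The libraries labelled CpG1668 and Dox lie between PBS and CpG1668+Dox on the first component.

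**Figure D2:**
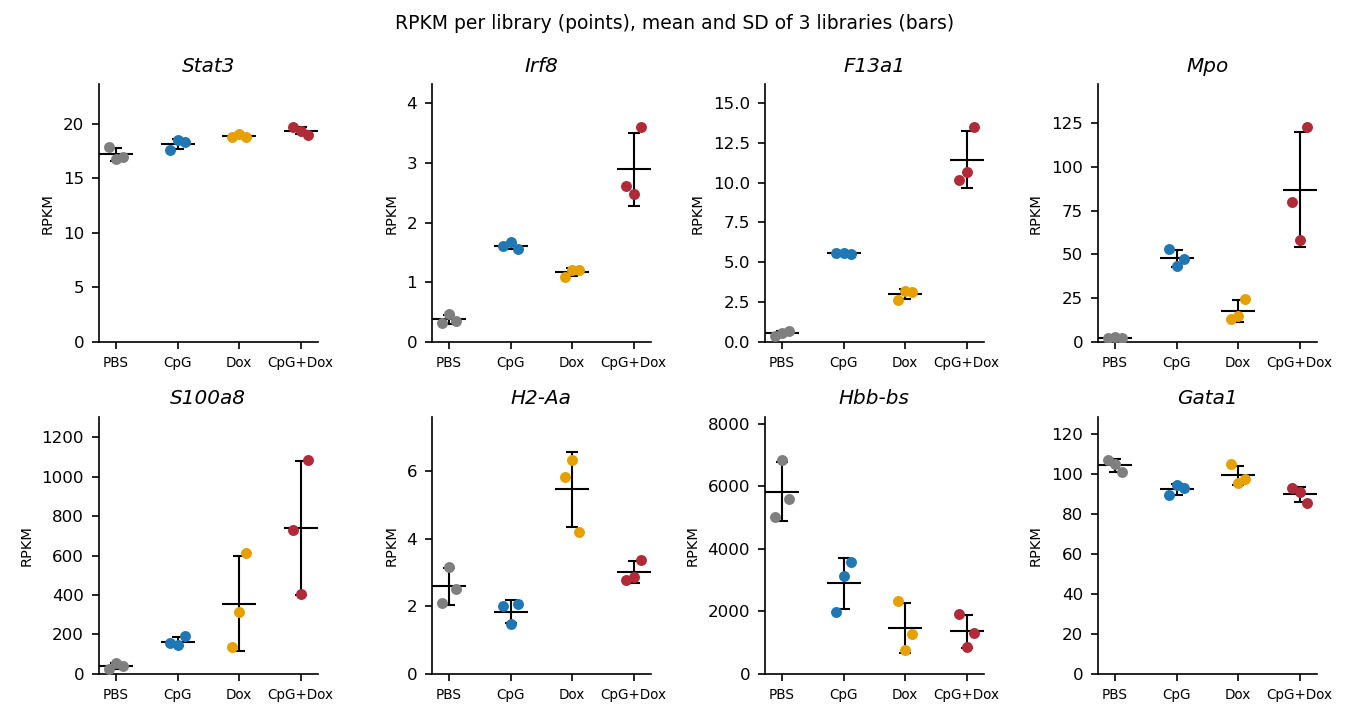
RPKM of 8 genes in each library (points), with the mean and SD of 3 libraries (bars), for PBS, CpG1668, Dox and CpG1668+Dox. Stat3 ranges from 16.8 to 19.7 over the 12 libraries, while Mpo rises from a mean of 2.26 in PBS to 86.9 in CpG1668+Dox.

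CpG1668 against PBS asks what TLR9 activation does to the leukaemia cells. After CpG1668, 21 of 23 monocyte markers and 4 of 14 myeloid transcription factors were called higher, and both list calls held with an estimated correlation (adjusted p = 0.024 for each). Also called were 5 of 9 primary granule genes and 10 of 15 late neutrophil genes as higher and 4 of 16 erythroid markers as lower, but these list calls were lost with an estimated correlation (adjusted p = 0.326, 0.432 and 0.432). Camera called 12 lists in this contrast, and fry kept 6 of these calls. Those of NF-kappaB targets (fry adjusted p = 0.055), MHC class I (0.062) and interferon-stimulated genes (0.080) were not kept. Nor were those of lysosome (0.085), mitochondrially encoded (0.089) and immediate-early and dissociation stress genes (0.342). The stem and leukaemia genes Gata2, Erg, Tal1 and Hlf were called lower and Cd93 higher, and their list was not called (camera adjusted p = 0.156). Of 12167 genes, 716 were called, 372 higher and 344 lower, and 178 and 14 of them changed at least 2-fold as a ratio of group means. The count was 456 and 381 without PBS 1 and PBS 2, and 397, 472 and 367 without CpG1668 1, 2 and 3. With the late neutrophil mean as a covariate, added after the data were seen, 100 genes were called.

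Of the 23 monocyte markers tested, 21 were called higher, 0 lower and 2 not called (22 higher and 0 lower adjusted over the list alone). The monocyte median log2 change was 1.17 (camera adjusted p = 3.3e-36, and adjusted p = 0.024 with an estimated correlation). F13a1, the A subunit of coagulation factor XIII, went from 0.54 ± 0.15 to 5.57 ± 0.0353 RPKM (log2 change 2.10, adjusted p = 7.4e-07), a 10.3-fold ratio of means. The Fc receptor gene Fcgr1 rose by 1.17 (adjusted p = 1.7e-05). Ms4a6c rose by 1.95 (adjusted p = 1.1e-05). Among 14 myeloid transcription factors, 4 were called higher (Irf8, Cebpa, Cebpb and Klf4) and 0 lower, or 8 and 0 adjusted over the list alone. The transcription factor median log2 change was 0.39 (camera adjusted p = 3.0e-08, and adjusted p = 0.024 with an estimated correlation). Irf8 rose by 0.93 (adjusted p = 2.2e-04), a 4.29-fold ratio of means, and Klf4 from 0.393 ± 0.032 to 2.17 ± 0.198 (1.19, adjusted p = 5.5e-06).

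Primary granule genes, which encode the enzymes of promyelocytes, showed some of the largest changes. Of 9 tested, 5 were called higher, 0 lower and 4 not called (6 higher and 1 lower adjusted over the list alone). The primary granule median log2 change was 2.18 (camera adjusted p = 7.3e-09, and adjusted p = 0.326 with an estimated correlation). Mpo (ENSMUSG00000009350.13, chromosome 11, 87793581 to 87804413, plus strand) went from 2.26 ± 0.141 to 47.8 ± 4.91 RPKM (3.90, adjusted p = 9.4e-06), a 21.1-fold ratio of means, and Ctsg from 1.16 ± 0.169 to 27.6 ± 0.862 (3.73, adjusted p = 1.6e-05). Of 15 late neutrophil genes, 10 were called higher, 0 lower and 5 not called (13 higher and 0 lower adjusted over the list alone). The late neutrophil median log2 change was 1.56 (camera adjusted p = 2.6e-11, and adjusted p = 0.432 with an estimated correlation). Ngp went from 23.1 ± 8.68 to 105 ± 17 (2.18, adjusted p = 0.019) and Chil3 from 6.39 ± 2.63 to 43.2 ± 3.59 (2.64, adjusted p = 7.7e-04). The pan-leucocyte gene Ptprc, chosen after its values were seen, was at 0.607 ± 0.161 in PBS and 2.07 ± 0.136 in CpG1668 (0.94, adjusted p = 6.2e-04). Of 3 more pan-leucocyte genes, chosen likewise, Itgb2 rose by 0.79 (adjusted p = 0.0059), and Laptm5 (0.12, adjusted p = 0.208) and Coro1a (0.05, adjusted p = 0.627) were not called. Ighm, the single member of 14 B and plasma cell markers that passed the filter, went from 0.461 ± 0.031 to 3.22 ± 0.301 (1.53, adjusted p = 7.5e-05). The Y-linked gene Eif2s3y, also chosen afterwards, was at 0.818 ± 0.335 and 1.2 ± 0.0537 and was not called (0.29, adjusted p = 0.158).

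In the TLR9 pathway list, 5 of 19 genes were called higher (Unc93b1, Irf5, Irf8, Tlr2 and Slc15a4) and 1 lower (Lgmn), the same numbers as adjusted over the list alone. The list includes another receptor gene, Tlr2, and shares Irf8 with the 14 myeloid transcription factors, while Tlr9 itself was below the filter. The TLR9 pathway median log2 change was 0.04 (camera adjusted p = 0.0095, and adjusted p = 0.503 with an estimated correlation). Unc93b1, which carries TLR9 to the endosome, went from 2.63 ± 0.185 to 5.93 ± 0.0663 (0.94, adjusted p = 2.8e-04), and the endosomal protease gene Lgmn fell (-0.37, adjusted p = 0.0020). Interferon-stimulated genes moved little, with 3 of 20 called higher (Stat2, Ifi27l2a and Trim30a), 0 lower and 3 higher adjusted over the list alone. The interferon-stimulated median log2 change was 0.09 (camera adjusted p = 0.0091, and adjusted p = 0.513 with an estimated correlation). Ifi27l2a rose from 1.53 ± 0.301 to 6.08 ± 0.761 (1.48, adjusted p = 1.7e-05). Lysosome genes (2 higher and 1 lower of 20, median 0.07, camera adjusted p = 0.0029) and MHC class I genes (4 higher and 0 lower of 17, median 0.04, camera adjusted p = 0.016) were higher. With an estimated correlation, these had adjusted p = 0.503 and adjusted p = 0.518, in that order, with 3 higher and 1 lower, then 4 and 0 adjusted over the list alone. NF-kappaB targets (1 higher and 0 lower of 15, median 0.17, camera adjusted p = 0.030) and immediate-early and dissociation stress genes (1 higher and 0 lower of 20, median 0.54, camera adjusted p = 3.1e-04) were higher. Given an estimated correlation, these had adjusted p = 0.363 and adjusted p = 0.554, in that order, with 2 higher and 0 lower, then 3 and 0 adjusted over the list alone. The immediate-early and dissociation stress list, fixed to read the handling of the cells, includes heat shock genes such as Hspa1b, which was not called (3.51, adjusted p = 0.086). It shares Egr1, Jun, Junb and Nr4a1 with the 14 myeloid transcription factors and Fos, Junb and Socs3 with the STAT3 targets. Mitochondrially encoded genes (0 higher and 1 lower of 13, median -0.18, camera adjusted p = 9.2e-04) were lower. An estimated correlation in place of the preset one gave adjusted p = 0.523, with 1 higher and 5 lower adjusted over the list alone.

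Among 16 erythroid markers, 0 were called higher and 4 lower, or 14 lower adjusted over the list alone. The erythroid median log2 change was -0.72 (camera adjusted p = 1.6e-07, and adjusted p = 0.432 with an estimated correlation). Car2 went from 405 ± 15.2 to 315 ± 7.0 (-0.36, adjusted p = 0.0046) and the transcription factor gene Gata1 from 104 ± 3.23 to 92.3 ± 2.82 (-0.17, adjusted p = 0.049). Of 15 stem, progenitor and leukaemia genes, 4 were called lower (Gata2, Erg, Tal1 and Hlf) and 1 higher (Cd93), or 5 and 1 adjusted over the list alone, and the list was not called (median -0.06, camera adjusted p = 0.156). Erg fell by 0.31 on the log2 scale (adjusted p = 0.016) and Cd93 rose by 0.88 (adjusted p = 2.9e-04). STAT3 targets went both ways, with 3 of 16 called higher (Socs3, Vegfa and Il4ra) and 3 lower (Bcl2l1, Ccnd2 and Tgfb1), or 5 and 4 adjusted over the list alone, and were not called as a list (camera adjusted p = 0.171). Of MHC class II genes, Ctss was the single one called (3 higher and 3 lower adjusted over the list alone), and the median of the list (-0.07) and its mean (0.09) differed in sign (camera adjusted p = 0.341). No mitosis or DNA replication gene was called by limma, with camera adjusted p = 0.307 and 0.461. Outside the lists, the largest rises included Plac8 (2.78, adjusted p = 6.8e-06) and Ifitm1 (2.32, adjusted p = 1.0e-04), and the largest falls Tubb3 (-1.23, adjusted p = 0.0059) and Serpinb1a (-1.21, adjusted p = 1.5e-04), whose reads can be shared with its close paralogs.

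Dox against PBS asks what switching on the Stat3 hairpin does alone, although the Stat3 transcript was not lower in these libraries. No group received Dox without holding the hairpin, so effects of the hairpin and of Dox itself cannot be told apart. In the libraries labelled Dox, 14 of 15 late neutrophil genes, 20 of 23 monocyte markers, 6 of 9 primary granule genes and 7 of 8 MHC class II genes were called higher, and 9 of 16 erythroid markers lower. These 5 list calls were lost with an estimated correlation (adjusted p = 0.189, 0.076, 0.239, 0.153 and 0.189, in that order). Fry kept 10 of the 13 list calls that camera made in this contrast. It did not keep those of MHC class I genes (adjusted p = 0.066), integrated stress response genes (0.194) and immediate-early and dissociation stress genes (0.194). Of 12167 genes, 728 were called, 480 higher and 248 lower, with 177 and 32 of them at least 2-fold. Quantile normalization gave 328 higher and 309 lower. The count was 385 and 404 without PBS 2 and PBS 3, 313 and 370 without Dox 2 and Dox 3, and 1 with the late neutrophil mean as a covariate.

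Late neutrophil genes had the largest median change of the 31 lists. Of 15 tested, 14 were called higher, 0 lower and 1 not called (15 higher and 0 lower adjusted over the list alone). The late neutrophil median log2 change was 2.33 (camera adjusted p = 1.0e-16, and adjusted p = 0.189 with an estimated correlation). S100a8 (ENSMUSG00000056054.9, chromosome 3, 90668978 to 90670035, plus strand) was at 39.2 ± 14.6 in PBS and 355 ± 242 in Dox (2.96, adjusted p = 0.0058), and Ngp at 23.1 ± 8.68 and 206 ± 119 (2.96, adjusted p = 0.0044), with a wide spread between the libraries labelled Dox. Of the 23 monocyte markers tested, 20 were called higher, 0 lower and 3 not called (22 higher and 1 lower adjusted over the list alone). The monocyte median log2 change was 0.79 (camera adjusted p = 8.8e-22, and adjusted p = 0.076 with an estimated correlation). F13a1 rose to 2.99 ± 0.301 (1.37, adjusted p = 7.3e-05) and Lyz2 from 22 ± 7.59 to 121 ± 37 (2.40, adjusted p = 0.0010). Primary granule genes had 6 of 9 called higher, 0 lower and 7 higher adjusted over the list alone. The primary granule median log2 change was 1.11 (camera adjusted p = 4.5e-07, and adjusted p = 0.239 with an estimated correlation). Mpo was at 17.4 ± 6.16 in Dox (2.45, adjusted p = 6.3e-04), a 7.69-fold ratio of means. Among myeloid transcription factors, 6 of 14 were called higher and 0 lower (10 higher adjusted over the list alone). The transcription factor median log2 change was 0.58 (camera adjusted p = 3.4e-08, and adjusted p = 0.049 with an estimated correlation). Irf8 rose 3.1-fold as a ratio of means (0.66, adjusted p = 0.0032). Of genes chosen after their values were seen, Ptprc was at 1.77 ± 0.316 (0.79, adjusted p = 0.0030), Itgb2 rose by 0.69 (adjusted p = 0.013), and Eif2s3y, at 0.922 ± 0.0693 (0.10, adjusted p = 0.687), Laptm5 (0.15, adjusted p = 0.129) and Coro1a (0.07, adjusted p = 0.433) were not called. Ighm, the single B and plasma cell marker that passed the filter, rose to 1.99 ± 0.354 (1.03, adjusted p = 0.0023).

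MHC class II genes were higher in the libraries labelled Dox, with 7 of 8 called higher, 0 lower and 7 higher adjusted over the list alone. The MHC class II median log2 change was 0.82 (camera adjusted p = 2.1e-07, and adjusted p = 0.153 with an estimated correlation). H2-Aa (ENSMUSG00000036594.15, chromosome 17, 34282744 to 34287823, minus strand) went from 2.59 ± 0.539 to 5.46 ± 1.11 (0.84, adjusted p = 0.0062), H2-Ab1 from 2.35 ± 0.752 to 5.66 ± 1.48 (0.99, adjusted p = 0.0070) and the invariant chain gene Cd74 from 9.25 ± 2.95 to 22.1 ± 6.22 (1.17, adjusted p = 0.011). Erythroid markers fell, with 9 of 16 called lower, 0 higher and 11 lower adjusted over the list alone. The erythroid median log2 change was -0.98 (camera adjusted p = 1.7e-11, and adjusted p = 0.189 with an estimated correlation). Hbb-bs (ENSMUSG00000052305.6, chromosome 7, 103826534 to 103828096, minus strand) fell from 5819 ± 938 to 1465 ± 790.0 (-2.12, adjusted p = 0.0083), a gene whose reads can be shared with Hbb-bt. The single-copy gene Alas2 fell from 78.7 ± 17 to 17.2 ± 11.4 (-2.29, adjusted p = 0.0087). Gata1, chosen here after its values were seen, was not called (-0.07, adjusted p = 0.415).

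STAT3 targets were not called as a list (camera adjusted p = 0.485), with Socs3, Vegfa and Hif1a called higher and Bcl2l1 lower among 16, or 6 higher and 5 lower adjusted over the list alone. Vegfa went from 6.32 ± 0.227 to 8.88 ± 0.263 (0.43, adjusted p = 0.0022) and Bcl2l1 from 17.5 ± 1.16 to 12 ± 1.14 (-0.51, adjusted p = 0.0028). Interferon-stimulated genes were split, with Ifi27l2a and Trim30a called higher and Isg15 and Rsad2 lower among 20, or 3 higher and 3 lower adjusted over the list alone. The median of that list was 0.02, its mean -0.08 and its camera adjusted p 0.781, and quantile normalization turned the median to -0.02. Isg15 fell from 69.2 ± 14.9 to 23.6 ± 13.6 (-1.64, adjusted p = 0.021). NF-kappaB targets (1 higher and 0 lower of 15, median 0.15, camera adjusted p = 0.0095), MHC class I genes (3 higher and 0 lower of 17, median 0.04, camera adjusted p = 0.045) and lysosome genes (2 higher and 0 lower of 20, median 0.09, camera adjusted p = 0.0057) were higher. Once the correlation was estimated, these had adjusted p = 0.189, adjusted p = 0.654 and adjusted p = 0.654, in that order, with 3 higher and 0 lower, then 4 and 0, then 6 and 1 adjusted over the list alone. Immediate-early and dissociation stress genes (1 higher and 0 lower of 20, median 0.53, camera adjusted p = 3.3e-04) and p53 genes (1 higher and 0 lower of 16, median 0.14, camera adjusted p = 0.0073) were higher. Fitted with an estimated correlation, these had adjusted p = 0.654 and adjusted p = 0.456, in that order, with 0 higher and 0 lower, then 7 and 1 adjusted over the list alone. Of the stress list, Socs3 was called (0.54, adjusted p = 0.048) and Jun was not (1.90, adjusted p = 0.115). Integrated stress response genes (2 higher and 0 lower of 20, median 0.12, camera adjusted p = 0.0083) and glycolysis and hypoxia genes (2 higher and 0 lower of 19, median 0.07, camera adjusted p = 0.018) were higher. With an estimated correlation, these had adjusted p = 0.675 and adjusted p = 0.654, in that order, with 2 higher and 0 lower, then 3 and 0 adjusted over the list alone. Stem, progenitor and leukaemia genes were not called as a list (camera adjusted p = 0.932), with Lmo2 lower (-0.35, adjusted p = 0.010) and Cd93 higher (0.73, adjusted p = 0.0023), and 2 higher and 1 lower adjusted over the list alone.

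CpG1668+Dox against PBS asks what the combination does, again with no fall in the Stat3 transcript of the libraries labelled CpG1668+Dox. In these, 22 of 23 monocyte markers and 9 of 14 myeloid transcription factors were called higher, and both list calls held with an estimated correlation (adjusted p = 0.026 for each). Also called higher were 15 of 15 late neutrophil, 7 of 9 primary granule, 13 of 20 lysosome and 7 of 19 TLR9 pathway genes, and called lower 15 of 16 erythroid markers. These list calls were lost with an estimated correlation (adjusted p = 0.195, 0.195, 0.229, 0.229 and 0.195, in that order). Camera made 14 list calls here, of which fry kept 11. Those of cholesterol synthesis (fry adjusted p = 0.090), immediate-early and dissociation stress (0.132) and ribosome biogenesis genes (0.313) were not kept. The stem and leukaemia genes Erg, Lmo2, Tal1 and Hlf were called lower and Cd93 higher, with no call for their list (camera adjusted p = 0.072). Of 12167 genes, 1890 were called, 1111 higher and 779 lower, with 284 and 40 at least 2-fold. Quantile normalization gave 984 higher and 1356 lower. The count was 9 with the late neutrophil mean as a covariate and 448 with the Y-linked mean.

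Of the 23 monocyte markers tested, 22 were called higher, 0 lower and 1 not called (23 higher and 0 lower adjusted over the list alone). The monocyte median log2 change was 1.84 (camera adjusted p = 1.9e-31, and adjusted p = 0.026 with an estimated correlation). F13a1 reached 11.4 ± 1.78 RPKM (3.01, adjusted p = 1.6e-08), a 21.2-fold ratio of means. Among myeloid transcription factors, 9 of 14 were called higher and 0 lower (11 higher adjusted over the list alone). The transcription factor median log2 change was 1.14 (camera adjusted p = 4.3e-09, and adjusted p = 0.026 with an estimated correlation). Irf8 reached 2.89 ± 0.614 (1.49, adjusted p = 1.5e-06), a 7.7-fold ratio of means, and Klf4 4.64 ± 0.355 (2.02, adjusted p = 1.6e-08). Of 9 primary granule genes, 7 were called higher, 0 lower and 2 not called (7 higher and 0 lower adjusted over the list alone). The primary granule median log2 change was 2.96 (camera adjusted p = 2.2e-08, and adjusted p = 0.195 with an estimated correlation). Mpo reached 86.9 ± 32.8 (4.69, adjusted p = 5.7e-07), a 38.5-fold ratio of means. For late neutrophil genes, 15 of 15 were called higher, also adjusted over the list alone (15). The late neutrophil median log2 change was 3.37 (camera adjusted p = 2.5e-16, and adjusted p = 0.195 with an estimated correlation). S100a9 went from 69.1 ± 24 to 1380.3 ± 644 (4.24, adjusted p = 8.6e-05). Chosen after their values were seen, Ptprc was at 3.94 ± 0.678 (1.61, adjusted p = 2.8e-06) and the Y-linked Eif2s3y at 1.76 ± 0.207 (0.62, adjusted p = 0.0028). Of the other pan-leucocyte genes, Itgb2 rose by 1.69 (adjusted p = 6.6e-06) and Laptm5 by 0.20 (adjusted p = 0.022), and Coro1a was not called (0.16, adjusted p = 0.050). Ighm reached 6.64 ± 1.73 (2.36, adjusted p = 7.0e-07).

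Lysosome genes were higher, with 13 of 20 called higher and 1 lower (14 and 1 adjusted over the list alone). The lysosome median log2 change was 0.19 (camera adjusted p = 3.5e-06, and adjusted p = 0.229 with an estimated correlation). Psap went from 57.7 ± 4.8 to 138 ± 16.2 (1.24, adjusted p = 2.2e-06). In the TLR9 pathway list, 7 of 19 genes were called higher and 1 lower (8 and 2 adjusted over the list alone). The TLR9 pathway median log2 change was 0.12 (camera adjusted p = 5.1e-04, and adjusted p = 0.229 with an estimated correlation). Unc93b1 rose to 9.05 ± 1.74 (1.46, adjusted p = 2.5e-06). MHC class II genes (3 higher and 0 lower of 8, median 0.32, camera adjusted p = 0.0013) and MHC class I genes (5 higher and 0 lower of 17, median 0.08, camera adjusted p = 0.0019) were higher. Given an estimated correlation, these had adjusted p = 0.275 and adjusted p = 0.346, in that order, with 3 higher and 0 lower, then 6 and 0 adjusted over the list alone. The class I gene B2m went from 229 ± 11.8 to 308 ± 18.3 (0.43, adjusted p = 1.0e-04). NF-kappaB targets (5 higher and 0 lower of 15, median 0.21, camera adjusted p = 0.0082), immediate-early and dissociation stress genes (4 higher and 0 lower of 20, median 0.81, camera adjusted p = 0.0019) and glycolysis and hypoxia genes (7 higher and 2 lower of 19, median 0.12, camera adjusted p = 0.0019) were higher. An estimated correlation in place of the preset one gave adjusted p = 0.195, adjusted p = 0.714 and adjusted p = 0.346, in that order, with 7 higher and 0 lower, then 4 and 0, then 10 and 2 adjusted over the list alone. The called members of the stress list were Fos, Zfp36, Socs3 and Nr4a1, the last also among the 9 transcription factors called higher. Cholesterol synthesis genes (0 higher and 1 lower of 20, median -0.09, camera adjusted p = 0.0082) and ribosome biogenesis genes (0 higher and 1 lower of 23, median -0.06, camera adjusted p = 0.023) were lower. Once the correlation was estimated, these had adjusted p = 0.502 and adjusted p = 0.798, in that order, with 0 higher and 1 lower, then 0 and 1 adjusted over the list alone.

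Of 16 erythroid markers, 0 were called higher, 15 lower and 1 not called (0 higher and 15 lower adjusted over the list alone). The erythroid median log2 change was -1.11 (camera adjusted p = 6.1e-12, and adjusted p = 0.195 with an estimated correlation). Slc4a1 went from 62.9 ± 21.5 to 10.3 ± 4.08 (-2.50, adjusted p = 0.0026) and Car2 from 405 ± 15.2 to 289 ± 3.55 (-0.49, adjusted p = 1.8e-04). STAT3 targets again went both ways, with 7 of 16 called higher and 3 lower (7 and 4 adjusted over the list alone), and were not called as a list (camera adjusted p = 0.272). Socs3 rose from 0.58 ± 0.141 to 2.65 ± 0.34 (1.21, adjusted p = 1.5e-04), and Bcl2l1 fell to 11.3 ± 0.186 (-0.59, adjusted p = 1.9e-04). Of 15 stem, progenitor and leukaemia genes, 4 were called lower (Erg, Lmo2, Tal1 and Hlf) and 1 higher (Cd93), or 6 and 1 adjusted over the list alone, and the list was not called (camera adjusted p = 0.072). Lmo2 fell from 88.6 ± 2.98 to 65.5 ± 1.49 (-0.43, adjusted p = 9.4e-04). Interferon-stimulated genes had 3 of 20 called higher and 2 lower, or 3 higher and 3 lower adjusted over the list alone. For that list, which was not called (camera adjusted p = 0.524), the median was 0.07 and the mean -0.01, and quantile normalization turned the median to -0.01. Rsad2 went from 30.3 ± 7.85 to 5.62 ± 1.59 (-2.25, adjusted p = 0.0039).

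CpG1668+Dox against CpG1668 asks what the Dox label added to TLR9 activation, where Stat3 itself was not called (0.09, adjusted p = 0.222). Called higher in the libraries labelled CpG1668+Dox were 15 of 15 late neutrophil genes, 19 of 23 monocyte markers and 6 of 14 myeloid transcription factors. Camera called 14 lists, and 0 of these calls held with an estimated correlation (adjusted p = 0.245, 0.068 and 0.068 for those 3). Fry kept 10 of the 14. It did not keep those of erythroid markers (adjusted p = 0.084), ribosome biogenesis genes (0.480), integrated stress response genes (0.324) and cholesterol synthesis genes (0.324). Of 12167 genes, 397 were called, 373 higher and 24 lower, with 96 and 1 at least 2-fold, and quantile normalization gave 307 higher and 66 lower. The count was 135, 150 and 264 without CpG1668 1, 2 and 3, and 151 and 133 without CpG1668+Dox 1 and 3. With the late neutrophil mean or the Y-linked mean as a covariate, limma called 0 genes, with 925 and 1170 at an unadjusted p under 0.05.

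All of the 15 late neutrophil genes tested were called higher, also adjusted over the list alone (15). The late neutrophil median log2 change was 1.81 (camera adjusted p = 1.6e-15, and adjusted p = 0.245 with an estimated correlation). S100a8 went from 164 ± 22.9 in CpG1668 to 741 ± 340.4 (2.06, adjusted p = 0.044) and S100a9 from 318 ± 53.7 to 1380.3 ± 644 (2.01, adjusted p = 0.039). Of the 23 monocyte markers tested, 19 were called higher, 0 lower and 4 not called (22 higher and 0 lower adjusted over the list alone). The monocyte median log2 change was 0.66 (camera adjusted p = 1.2e-22, and adjusted p = 0.068 with an estimated correlation). F13a1 rose by 0.91 (adjusted p = 0.0017) and the integrin gene Itgam by 1.23 (adjusted p = 0.0079). Myeloid transcription factors had 6 of 14 called higher (9 adjusted over the list alone). The transcription factor median log2 change was 0.38 (camera adjusted p = 2.1e-07, and adjusted p = 0.068 with an estimated correlation). Irf8 (0.57, adjusted p = 0.0096) and Klf2 (1.01, adjusted p = 0.0053) were among them. Primary granule genes had Cebpe as the single called member (1.30, adjusted p = 0.028), and 7 of 9 higher adjusted over the list alone. The primary granule median log2 change was 0.78 (camera adjusted p = 1.3e-04, and adjusted p = 0.339 with an estimated correlation). Mpo, chosen here after its values were seen, was not called (0.79, adjusted p = 0.129). Ptprc, chosen after its values were seen, rose by 0.68 (adjusted p = 0.0096) and Itgb2, chosen likewise, by 0.90 (adjusted p = 0.0066), while Eif2s3y (0.33, adjusted p = 0.156), Laptm5 (0.08, adjusted p = 0.528) and Coro1a (0.11, adjusted p = 0.320) were not called. Ighm rose by 0.84 (adjusted p = 0.0078).

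Lysosome genes (4 higher and 0 lower of 20, median 0.12, camera adjusted p = 2.5e-06) and TLR9 pathway genes (4 higher and 0 lower of 19, median 0.12, camera adjusted p = 1.6e-04) were higher. Fitted with an estimated correlation, these had adjusted p = 0.245 and adjusted p = 0.245, in that order, with 8 higher and 0 lower, then 8 and 0 adjusted over the list alone. MHC class II genes (2 higher and 0 lower of 8, median 0.53, camera adjusted p = 4.9e-06) and MHC class I genes (2 higher and 0 lower of 17, median 0.05, camera adjusted p = 0.0097) were higher. With an estimated correlation, these had adjusted p = 0.245 and adjusted p = 0.478, in that order, with 7 higher and 0 lower, then 5 and 0 adjusted over the list alone. Mast cell, basophil and eosinophil markers (3 higher and 0 lower of 8, median 0.27, camera adjusted p = 4.5e-04) were higher. Given an estimated correlation, these had adjusted p = 0.301, with 5 higher and 0 lower adjusted over the list alone. Among these markers, Cpa3 was at 417 ± 19.6 in CpG1668 and 563 ± 8.16 in CpG1668+Dox (0.43, adjusted p = 0.040) and Mcpt8 was at 0.854 ± 0.357 and 2.53 ± 0.339 (0.94, adjusted p = 0.014). Glycolysis and hypoxia genes (2 higher and 0 lower of 19, median 0.06, camera adjusted p = 9.8e-04) and integrated stress response genes (0 higher and 0 lower of 20, median 0.12, camera adjusted p = 0.025) were higher. An estimated correlation in place of the preset one gave adjusted p = 0.339 and adjusted p = 0.744, in that order, with 5 higher and 0 lower, then 0 and 0 adjusted over the list alone. Erythroid markers (0 higher and 0 lower of 16, median -0.39, camera adjusted p = 2.7e-09), ribosome biogenesis genes (0 higher and 0 lower of 23, median -0.05, camera adjusted p = 2.5e-04) and cholesterol synthesis genes (0 higher and 0 lower of 20, median -0.05, camera adjusted p = 9.7e-04) were lower. Once the correlation was estimated, these had adjusted p = 0.245, adjusted p = 0.662 and adjusted p = 0.424, in that order, with 0 higher and 9 lower, then 0 and 0, then 0 and 0 adjusted over the list alone. The interferon-inducible gene Apol11b had the largest named fall, from 7.13 ± 1.93 to 1.73 ± 0.709 (-1.58, adjusted p = 0.038), and the haem synthesis gene Fech fell too (-0.35, adjusted p = 0.049).

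CpG1668+Dox against Dox asks what TLR9 activation added in libraries with the Dox label, and Stat3 was not called (0.03, adjusted p = 0.783). In the libraries labelled CpG1668+Dox, 20 of 23 monocyte markers and 6 of 14 myeloid transcription factors were called higher, and both list calls held with an estimated correlation (adjusted p = 0.023 for each). Also called higher were 6 of 9 primary granule genes and 6 of 19 TLR9 pathway genes, whose list calls were lost with an estimated correlation (adjusted p = 0.191 and 0.185). Camera called 17 lists in this contrast, and fry kept 8 of these calls. Those of late neutrophil (fry adjusted p = 0.121), p53 (0.121), megakaryocyte (0.121), glycolysis and hypoxia (0.151) and erythroid genes (0.275) were not kept. Nor were those of cholesterol synthesis (0.275), integrated stress response (0.323), mitochondrially encoded (0.323) and mitosis genes (0.371). Of the stem and leukaemia genes Gata2, Tal1 and Hlf were called lower and Cd93 higher, and of the MHC class II genes H2-Aa and H2-Ab1 lower and Ctss higher. The stem list was called by camera (adjusted p = 0.010, and adjusted p = 0.191 with an estimated correlation) and the MHC class II list was not (0.785). Of 12167 genes, 423 were called, 342 higher and 81 lower, with 147 and 4 at least 2-fold. The count was 258 without CpG1668+Dox 1. It was 165 with the late neutrophil mean and 4 with the Y-linked mean as a covariate.

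Of the 23 monocyte markers tested, 20 were called higher, 0 lower and 3 not called (22 higher and 0 lower adjusted over the list alone). The monocyte median log2 change was 1.01 (camera adjusted p = 3.7e-40, and adjusted p = 0.023 with an estimated correlation). Fcgr1 went from 0.891 ± 0.0595 in Dox to 2.65 ± 0.422 (0.94, adjusted p = 1.5e-04) and F13a1 from 2.99 ± 0.301 to 11.4 ± 1.78 (1.64, adjusted p = 1.2e-05). Among 14 myeloid transcription factors, 6 were called higher, 0 lower and 8 not called (9 higher and 1 lower adjusted over the list alone). The transcription factor median log2 change was 0.36 (camera adjusted p = 2.4e-08, and adjusted p = 0.023 with an estimated correlation). Irf8 rose 2.48-fold as a ratio of means (0.84, adjusted p = 5.6e-04). In the primary granule list, 6 of 9 genes were called higher (6 adjusted over the list alone). The primary granule median log2 change was 1.85 (camera adjusted p = 7.9e-09, and adjusted p = 0.191 with an estimated correlation). Mpo rose 5.0-fold as a ratio of means (2.24, adjusted p = 5.1e-04). Of 15 late neutrophil genes, Chil3 alone was called (1.93, adjusted p = 0.0071), and 13 were higher adjusted over the list alone. The late neutrophil median log2 change was 1.04 (camera adjusted p = 1.1e-08, and adjusted p = 0.415 with an estimated correlation). Chosen after their values were seen, Ptprc rose by 0.83 (adjusted p = 0.0015), Itgb2 by 1.00 (adjusted p = 0.0014) and the Y-linked Eif2s3y by 0.52 (adjusted p = 0.023), and Laptm5 (0.05, adjusted p = 0.769) and Coro1a (0.08, adjusted p = 0.527) were not called. Ighm rose by 1.34 (adjusted p = 2.8e-04).

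TLR9 pathway genes (6 higher and 0 lower of 19, median 0.12, camera adjusted p = 1.6e-06) and lysosome genes (4 higher and 0 lower of 20, median 0.09, camera adjusted p = 2.6e-06) were higher. Fitted with an estimated correlation, these had adjusted p = 0.185 and adjusted p = 0.292, in that order, with 7 higher and 0 lower, then 7 and 0 adjusted over the list alone. MHC class I genes (4 higher and 0 lower of 17, median 0.05, camera adjusted p = 0.0032) and interferon-gamma-inducible genes (2 higher and 0 lower of 12, median 0.06, camera adjusted p = 0.0071) were higher. With an estimated correlation, these had adjusted p = 0.415 and adjusted p = 0.407, in that order, with 5 higher and 0 lower, then 3 and 0 adjusted over the list alone. MHC class II genes were not called as a list (median -0.27, camera adjusted p = 0.785, 3 higher and 4 lower adjusted over the list alone), with H2-Aa at 5.46 ± 1.11 and 3.01 ± 0.33 (-0.68, adjusted p = 0.021), H2-Ab1 lower and Ctss higher. Stem, progenitor and leukaemia genes (1 higher and 3 lower of 15, median -0.08, camera adjusted p = 0.010), erythroid markers (0 higher and 1 lower of 16, median -0.14, camera adjusted p = 0.0018) and megakaryocyte markers (0 higher and 1 lower of 6, median -0.14, camera adjusted p = 0.024) were lower. Given an estimated correlation, these had adjusted p = 0.191, adjusted p = 0.532 and adjusted p = 0.415, in that order, with 1 higher and 3 lower, then 0 and 5, then 0 and 1 adjusted over the list alone. Gata2 (-0.23, adjusted p = 0.019), Tal1 and Hlf were called lower in the stem and leukaemia list and Cd93 higher (0.67, adjusted p = 0.0019). Car2 (-0.33, adjusted p = 0.0094) and Gp5 (-0.19, adjusted p = 0.025) were the called members of the erythroid and megakaryocyte lists. Mitosis genes (0 higher and 0 lower of 24, median 0.05, camera adjusted p = 0.0061) and glycolysis and hypoxia genes (4 higher and 1 lower of 19, median 0.05, camera adjusted p = 0.0094) were higher. An estimated correlation in place of the preset one gave adjusted p = 0.640 and adjusted p = 0.514, in that order, with 0 higher and 0 lower, then 4 and 1 adjusted over the list alone. Integrated stress response genes (0 higher and 0 lower of 20, median -0.12, camera adjusted p = 0.0011) and p53 genes (0 higher and 0 lower of 16, median -0.12, camera adjusted p = 0.0061) were lower. Once the correlation was estimated, these had adjusted p = 0.586 and adjusted p = 0.415, in that order, with 0 higher and 0 lower, then 0 and 0 adjusted over the list alone. Mitochondrially encoded genes (0 higher and 0 lower of 13, median -0.11, camera adjusted p = 0.0061) and cholesterol synthesis genes (0 higher and 0 lower of 20, median -0.07, camera adjusted p = 0.0094) were lower. Fitted with an estimated correlation, these had adjusted p = 0.602 and adjusted p = 0.532, in that order, with 0 higher and 0 lower, then 0 and 0 adjusted over the list alone.

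**Figure D3:**
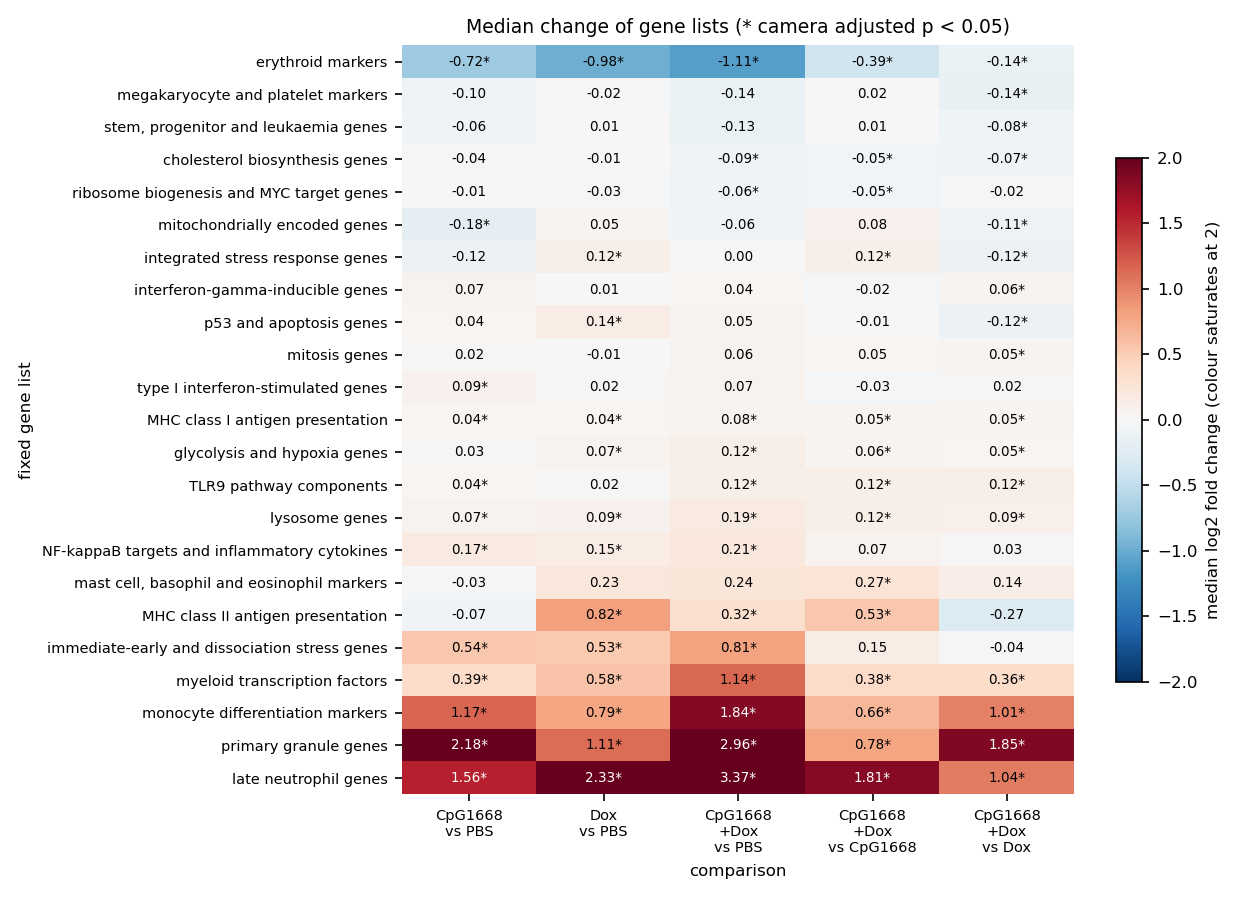
Median log2 fold change of 23 gene lists (vertical axis) in 5 pairwise comparisons (horizontal axis), as coloured cells with the value in each, for lists with a camera adjusted p under 0.05 (star) in at least 1 comparison. Late neutrophil genes have medians of 2.33 in Dox against PBS and 3.37 in CpG1668+Dox against PBS, while erythroid markers have -0.98 and -1.11.

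The interaction asks whether the Dox label changed the response to CpG1668. No gene met the threshold. Limma called 0 of 12167 genes, with a smallest adjusted p of 0.316 and 812 genes at an unadjusted p under 0.05. It called 1 gene without CpG1668 1 or without CpG1668+Dox 1. Among genes with the smallest p that did not pass, Ypel3 had 0.76 (adjusted p = 0.316) and Ddit4 -0.66 (adjusted p = 0.316). Mpo (-1.66, adjusted p = 0.419), Irf8 (-0.09, adjusted p = 0.978) and Vegfa (-0.38, adjusted p = 0.419) did not pass either. By camera, 7 lists had a negative and 1 a positive interaction, with 0 members called over all genes in each, and none held with an estimated correlation (adjusted p = 0.810) or with fry (0.808). Adjusted over the list alone, at least 1 member passed, an interferon-stimulated gene that was lower. The number of lists called was 5 without PBS 1, 3 without CpG1668 3, 3 without CpG1668+Dox 2 and 12 without Dox 3, and 3 with quantile normalization and 5 with no filter. DNA methylation and chromatin genes, named in the title's question on epigenetic reprogramming, were among these lists (median -0.04, camera adjusted p = 0.042). They were not called as a list in the 5 pairwise comparisons (camera adjusted p = 0.141, 0.159, 0.369, 0.622 and 0.684). Of 23 members, Kdm6b (0.19, adjusted p = 0.035) and Kmt2a (0.24, adjusted p = 0.046) were called higher in Dox against PBS. In CpG1668+Dox against PBS, Eed (0.16, adjusted p = 0.016) and Kmt2a (0.22, adjusted p = 0.034) were called higher and Hdac1 lower (-0.12, adjusted p = 0.029).

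Genes called for CpG1668 both with and without the Dox label went the same way. Across genes, which are not independent replicates, the log2 changes of CpG1668 against PBS and of CpG1668+Dox against Dox had a Pearson r of 0.671 and a Spearman rho of 0.43, with a slope of 0.527. They shared 238 genes called higher (10.5 if independent) and 46 called lower (2.29 if independent), and 0 were called in opposite directions. Changes with the Dox label, in Dox against PBS and in CpG1668+Dox against CpG1668, had r of 0.655 and rho of 0.447, with 239 shared higher (14.7 if independent), 13 shared lower (0.489 if independent) and 0 opposite. CpG1668 and Dox also resembled each other against their common PBS controls, with r of 0.805 where 100 simulations without any effect gave 0.501. Their covariance was 0.0408, against 0.0041 in the simulations, a difference of 0.0368. They shared 235 genes called higher (14.7 if independent) and 122 called lower (7.01 if independent), with 1 opposite. The 3 PBS libraries were not split, since 1 of the parts would hold a single library, so part of the excess may come from the shared controls.

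**Figure D4:**
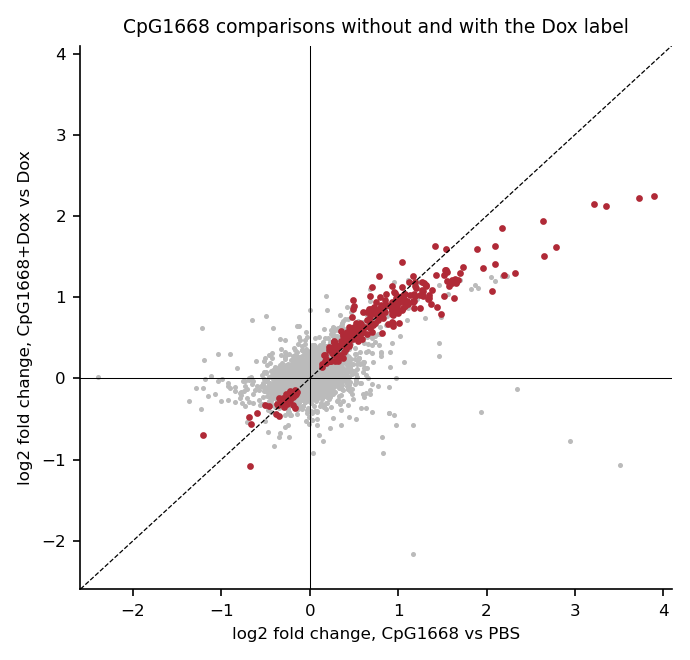
Log2 fold change of CpG1668 against PBS (horizontal axis) and of CpG1668+Dox against Dox (vertical axis) for 12167 genes, with genes called in both in red and equality as a dashed line. The 238 genes called higher and the 46 called lower in both lie in the same quadrants, and 0 are opposite.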

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

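The tests of Y-linked genes, of the late erythroid genes, and of swapped labels and admixed neutrophils for Stat3 were chosen only after the result was seen. The permutation test of Stat3 with the Dox label was planned. Outlying libraries were not tested for, although Dox 1 correlated best with a library of another group, CpG1668 3. Each group had 3 libraries, and no deposited file was left unused. The interaction stood out for 8 gene lists, since camera found their response to Dox to differ with and without CpG1668. The median log2 interaction was -0.16 for monocyte markers (adjusted p = 0.0050), -0.33 for primary granule genes (0.0050), -0.52 for late neutrophil genes (0.018), -0.34 for immediate-early and dissociation stress genes (0.0025), -0.17 for p53 and apoptosis genes (0.0017), -0.07 for type I interferon-stimulated genes (0.030) and -0.04 for DNA methylation and chromatin genes (0.042). It was 0.58 for erythroid markers (0.018). With an estimated correlation each had an adjusted p of 0.810, and by fry 0.808, and 0 of their genes were called. Without Dox replicate 3 the camera direction of the late neutrophil genes reversed (median -0.157, adjusted p = 0.982), and their call was also lost without PBS 1, CpG1668 3 or CpG1668+Dox 2, with adjusted p from 3.6e-07 to 0.982 over the 12 libraries left out in turn. Leaving out 1 library ended the call for 6 of 12 libraries in interferon-stimulated genes, 4 in monocyte markers, 2 in primary granule genes, 8 in DNA methylation and chromatin genes, 3 in immediate-early and dissociation stress genes, 4 in erythroid markers and 0 in p53 and apoptosis genes. The medians then ran from -0.100 to -0.022, -0.268 to -0.127, -0.626 to -0.071, -0.059 to -0.020, -0.496 to -0.006, 0.305 to 0.774 and -0.221 to -0.129, in that order. Of 100 regroupings of the 12 libraries, the real one included, 22 gave at least the 812 genes at an unadjusted p under 0.05 of the real grouping, the highest of the others 2453. Regroupings with several times the real number point to a structure of the samples, which here holds the treatment effects themselves (1890 genes called in CpG1668+Dox against PBS), since regroupings mix the treatments. The regroupings are therefore no test of the interaction, and whether chance can be excluded stays open.

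The numbers of called genes were compared with those of other splits of the 6 libraries. In each of the 6 pairwise contrasts 1 of 10 splits, the real one, gave as many genes. The real count was 716 for CpG1668 against PBS and the highest of the others 1. It was 728 and 0 for Dox against PBS, 1890 and 0 for CpG1668+Dox against PBS, 397 and 1 for CpG1668+Dox against CpG1668, 423 and 1 for CpG1668+Dox against Dox, and 190 and 0 for CpG1668 against Dox. The 10 splits are too few for a share under 0.05.

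Myeloid genes were called higher in the CpG1668, Dox and CpG1668+Dox libraries (monocyte markers 21, 20 and 22 of 23 against PBS, list adjusted p = 0.024, 0.076 and 0.026 with an estimated correlation). Scaling is argued against, since 100% of the monocyte markers called higher in CpG1668+Dox against PBS stayed so under both other scalings. Y-linked transcripts (Eif2s3y reached 1.76 ± 0.207 RPKM in CpG1668+Dox) may come with admixed cells. In the libraries labelled Dox their mean log2 RPKM (-2.03 to -1.84) lay within the range of PBS (-2.41 to -1.38). The mean log2(RPKM + 1) of late neutrophil genes was higher there (3.65 to 5.21 against 1.94 to 2.48), so no rise of Y-linked transcripts went with it. These transcripts were low and spread widely in PBS, so a small share of such cells could be missed. Within-group correlations of the Y-linked mean over 12 libraries leave open whether admixed cells brought the myeloid genes. For late neutrophil genes r was 0.307 (exact permutation p = 0.231 over 1296 arrangements, rho 0.350, p = 0.306, and r = 0.161 without PBS 1 and PBS 2). For primary granule genes it was 0.317 (p = 0.175, rho 0.510, p = 0.116, and 0.447 without those 2), for monocyte markers 0.678 (p = 0.0779, rho 0.622, p = 0.0934, and 0.363) and for the late erythroid genes named below, to which this relation was narrowed after its result was seen, 0.291 (p = 0.224, rho 0.308, p = 0.350, and 0.156). Each had an adjusted p of 0.231 over these 4 relations. The B, dendritic, T and NK, and stromal lists kept 1, 2, 1 and 2 members of 14, 16, 17 and 18. Of these Ighm (0.461 ± 0.031 in PBS and 6.64 ± 1.73 in CpG1668+Dox, adjusted p = 7.0e-07) and Sirpa (4.46 ± 0.847 and 14.5 ± 2.88, adjusted p = 5.2e-05) were called higher, and Cd1d1, Nkg7, Kdr and Tek were not called (0.14, 0.20, -0.11 and -0.17). So few members cannot show whether such cells were present, and admixture stays open. Host cells of NSG mice, which lack an intact Il2rg, cannot be told apart, because Il2rg (ratio 0.967 of CpG1668+Dox to PBS) starts too high to show a small share. A pure sort on GFP and mCherry would remove host cells, but its purity is not given. Handling stress, which the immediate-early and dissociation stress list reads (median log2 change 0.54, 0.53 and 0.81 against PBS), and differentiation of the leukaemia cells themselves stay open and untested.

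The late erythroid genes Hbb-bs, Hbb-bt, Alas2 and Slc4a1 were called lower in the libraries labelled Dox and CpG1668+Dox than in PBS. Gata1, Klf1, Epor, Rhag, Car1 and Ermap showed at most 0.111 of the median fall of Hbb-bs, Hbb-bt, Alas2 and Slc4a1 (medians of -0.09 and -2.26 in Dox against PBS, and -0.26 and -2.32 in CpG1668+Dox against PBS). Both sets were chosen after their values were seen, the first from genes not called in Dox against PBS. The share therefore describes these genes and cannot test an equal fall of the whole erythroid programme. An unequal fall stays open, since 5 of those 6 genes were called lower in CpG1668+Dox against PBS, from -1.03 to -0.04 over the 6, against 0 of 6 in Dox against PBS (-0.96 to 0.12). Reads exchanged between haemoglobin paralogs are argued against as the source of the haemoglobin fall, since the summed RPKM of 12 haemoglobin genes, which such an exchange would leave in place, was lower on the log2 scale in Dox (-1.92, SE 0.39) and in CpG1668+Dox (-2.02, SE 0.39) against PBS. A smaller share of haemoglobin-rich cells and a change of maturation inside the leukaemia both stay open, because Alas2 and Slc4a1 (to which this test was narrowed after its result was seen) would follow Hbb-bs within groups (median r = 0.979, lowest 0.962) under either. If haemoglobin-rich cells came from the host, a pure sort on GFP and mCherry would remove them, but its purity is not given.

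The Stat3 transcript was not lower in the libraries labelled Dox and CpG1668+Dox. Labels swapped between libraries with and without Dox are argued against only for a large fall of Stat3, since the highest value was 1.17 times the lowest over 12 libraries. A swap with a small fall stays open, since libraries with the Dox label (18.8 to 19.7 RPKM) all lay above those without (16.8 to 18.5). Stat3 from admixed neutrophils is argued against too, since S100a8 ranged 7.97-fold over the 6 Dox-labelled libraries (from 136 to 1087 RPKM) while the slope of Stat3 on S100a8 over that range came to 1.10% of mean Stat3. A hairpin that was not induced, a fall of STAT3 protein without a fall of the transcript, or recovery by the day of harvest might each give this and were not tested.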

How the results depend on the processing

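The covariates for late neutrophil genes and for Y-linked genes, and the contrast of CpG1668 against Dox, were chosen after the data were seen. For the 859 results of named genes in the 6 planned contrasts, the alternatives fixed beforehand gave 16801 values. Of these 15745 kept their side of the threshold, 913 were no longer called, 143 became called and 0 reversed. Direction was compared only for results that the main fit called, and for lists it was the camera direction. For the 186 results of lists in these contrasts the same alternatives gave 4037 values. Of the list values 3686 kept their side of the threshold, 205 were no longer called, 145 became called and 1 reversed. Without Dox replicate 3, the camera direction reversed for the late neutrophil interaction (median -0.157, adjusted p = 0.982) and for mitosis genes in CpG1668 against Dox (-0.0405, adjusted p = 0.936). Fewer samples were compared in both. Over the libraries left out, these medians ran from -0.910 to -0.157 and from -0.0405 to 0.0523.

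Stat3 stayed higher with the Dox label under each alternative run, from 0.09 to 0.12. Counts of called genes moved more. A mean RPKM of at least 5, with fewer genes tested, gave 455 for CpG1668 against PBS, 382 for Dox against PBS, 1155 for CpG1668+Dox against PBS, 185 for CpG1668+Dox against CpG1668 and 180 for CpG1668+Dox against Dox. No filter, with more genes tested, gave 434 for Dox against PBS, 658 for CpG1668+Dox against Dox, 12 for the interaction and 102 for CpG1668 against Dox. A fit of only the groups compared, with fewer samples, gave 355 for Dox against PBS, 257 for CpG1668+Dox against CpG1668, 216 for CpG1668+Dox against Dox and 72 for CpG1668 against Dox. The replicate block gave 78 for CpG1668 against Dox. Same-numbered libraries did not pair (3 of 12 correlated best with a library of their own number), and the cause was not tested.

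With the late neutrophil covariate the counts were 100 for CpG1668 against PBS, 1 for Dox against PBS, 9 for CpG1668+Dox against PBS, 0 for CpG1668+Dox against CpG1668 (925 at an unadjusted p under 0.05 by limma), 165 for CpG1668+Dox against Dox and 87 for CpG1668 against Dox. With the Y-linked covariate they were 511 for CpG1668 against PBS and 690 for Dox against PBS, nearer to the 716 and 728 without it. They were 448 for CpG1668+Dox against PBS, 0 for CpG1668+Dox against CpG1668 (1170 at an unadjusted p under 0.05 by limma), 4 for CpG1668+Dox against Dox and 77 for CpG1668 against Dox. Both covariates differ between the groups, so they take up treatment effects too, and the cause was not tested.

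Leaving out 1 library gave 367 to 762 genes for CpG1668 against PBS, 313 to 774 for Dox against PBS, 1363 to 1906 for CpG1668+Dox against PBS, 133 to 459 for CpG1668+Dox against CpG1668, 258 to 429 for CpG1668+Dox against Dox, 0 to 1 for the interaction and 33 to 236 for CpG1668 against Dox. The Stat3 difference ran from 0.0985 to 0.122. The correlation across genes ran from 0.609 to 0.682 for the CpG1668 responses and from 0.603 to 0.674 for the Dox responses, and was 0.585 and 0.557 without the filter, with more genes tested. Depth limits genes near 0.086 to 0.099 RPKM, such as Tlr9 in PBS.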

Other observations

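The contrast of CpG1668 with Dox, and the genes Xist, Ddx3y and Fcer1a, were chosen only after the data were seen. The single treatments differed in some myeloid and antigen-presenting genes, with no fall of Stat3 in the libraries labelled Dox. Some monocyte markers (5 of 23) and primary granule genes (3 of 9) were called higher in CpG1668, and some MHC class II genes (4 of 8) higher in Dox. Camera called 13 lists, and 0 of these calls held with an estimated correlation (adjusted p = 0.431, 0.611 and 0.589 for those 3 lists) and 1 with fry. Leaving out 1 library, the number of lists called ran from 7 (without Dox 3) to 15 (without Dox 1). Limma called 190 of 12167 genes, 43 higher and 147 lower in CpG1668, where median-of-ratios scaling gave 52 and 91 and quantile normalization 55 and 101. The count was 33, 70 and 92 without CpG1668 1, 2 and 3, and 69 and 76 without Dox 2 and Dox 3.

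Of 23 monocyte markers, 5 were called higher, 0 lower and 18 not called (12 higher and 0 lower adjusted over the list alone). The monocyte median log2 change was 0.32 (camera adjusted p = 1.2e-11, and adjusted p = 0.431 with an estimated correlation). Of 9 primary granule genes, 3 were called higher, 0 lower and 6 not called (5 higher and 1 lower adjusted over the list alone). The primary granule median log2 change was 1.06 (camera adjusted p = 5.1e-04, and adjusted p = 0.611 with an estimated correlation). Mpo was higher by 1.45 (adjusted p = 0.019), and Ctsg by 1.53 (adjusted p = 0.018). MHC class II genes (0 higher and 4 lower of 8, median -0.65, camera adjusted p = 3.7e-04) were lower. With an estimated correlation, these had adjusted p = 0.589, with 0 higher and 4 lower adjusted over the list alone. Fry kept that call (adjusted p = 0.037) and did not keep those of monocyte markers (0.072), primary granule genes (0.216), integrated stress response genes (0.095) or late neutrophil genes (0.271). H2-Aa was at 1.84 ± 0.331 in CpG1668 and 5.46 ± 1.11 in Dox (-1.17, adjusted p = 0.0049), and H2-Ab1 at 1.48 ± 0.12 and 5.66 ± 1.48 (-1.40, adjusted p = 0.0049). Integrated stress response genes (0 higher and 3 lower of 20, median -0.23, camera adjusted p = 4.2e-07) were lower. Given an estimated correlation, these had adjusted p = 0.611, with 0 higher and 14 lower adjusted over the list alone. Asns, Psat1 and Pck2 were called lower in CpG1668. Late neutrophil genes had 0 called members. The late neutrophil median log2 change was -0.78 (camera adjusted p = 3.3e-04, and adjusted p = 0.649 with an estimated correlation).

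Chemokine genes were too few for a list test. Ccl9 was higher in each treated group against PBS, by 1.64 (adjusted p = 7.4e-07) in CpG1668, by 1.15 (adjusted p = 5.2e-05) in Dox and by 2.34 (adjusted p = 1.6e-08) in CpG1668+Dox. It reached 6.13 ± 0.531 RPKM from 0.404 ± 0.0848 in PBS. The mast cell gene Fcer1a was abundant in each group, at 629.6 ± 46.9 in PBS, 619 ± 23.9 in CpG1668, 755 ± 77 in Dox and 709 ± 18.8 in CpG1668+Dox. The basophil and mast cell protease genes Mcpt8, at 0.326 ± 0.13 in PBS and 2.53 ± 0.339 in CpG1668+Dox (1.41, adjusted p = 1.7e-04) and Prss34, at 0.425 ± 0.207 and 3.25 ± 0.325 (1.58, adjusted p = 5.6e-04), were low and were called higher in CpG1668+Dox than in PBS. The X-linked transcript Xist was at 58 ± 7.13 in PBS, 56.8 ± 10.6 in CpG1668, 47 ± 7.43 in Dox and 48.2 ± 4.3 in CpG1668+Dox, beside low values of the Y-linked Ddx3y, at 0.617 ± 0.26 in PBS, 0.782 ± 0.0793 in CpG1668, 0.634 ± 0.0746 in Dox and 1.23 ± 0.184 in CpG1668+Dox.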
